A study of Arabidopsis thaliana with 6 samples.

How the data were processed

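RNA-seq libraries of whole 7-day-old Arabidopsis seedlings were compared between 2 genotypes, WT and lon1-2, with 3 biological replicates each. Per the labels' protocols, libraries were made with a stranded poly(A) mRNA kit from RNA with an integrity number of at least 7 and sequenced as paired reads of 125 or 150 bases. Nothing in the labels says whether a replicate was a plate, a sowing or a pool of seedlings, and p-values measure the spread between these samples.

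The authors deposited whole-number counts per gene for each library, which are not normalised. The authors also deposited FPKM for each library, which divide counts by gene length and by the library total. Per the submitters' processing notes, the reads were handled with Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq against TAIR10; versions, the role of each tool and the strand setting of the counting are not given in the sources used here. Overlapping and antisense genes may therefore share counts. Over 17673 genes, the ratio of count over total to FPKM was constant across libraries within a relative tolerance of 1e-06 for 100% of genes, so the FPKM hold no scaling beyond the total count. The count tables list 27444 genes, all of the nuclear chromosomes. Genes encoded in the organelles, for which a comparison had been planned, were not analysed here. Poly(A) libraries would measure them poorly in any case.

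Gene names and products came from the RefSeq annotation of TAIR10.1, matched by locus identifier, which was found for all 27444 genes; coordinates are given for LON1 alone, from TAIR10.1. Where a list gave a symbol in common use, that symbol was printed. To see which genes share sequence, exonic 50-mers of the named genes were searched in the whole genome. Among these named genes, shares above 3% were 18.1% for MTHSC70-2, 6.06% for TPS12, 5.48% for FRO5, 5.19% for SAUR21, 3.99% for LDOX, 3.60% for AT1G77530 and 3.51% for AT1G77520; for LON4 the share was 2.69%.

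Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15), scaled by TMM and fitted with a robust quasi-likelihood model with genotype as the only term. P-values were adjusted by Benjamini and Hochberg over all 19940 tested genes, and genes were called at an adjusted p under 0.05. CPM are edgeR's library-size normalised counts after TMM scaling, and the standard error of a log2 fold change was derived from its F statistic. Total counts were 22909040, 23226320 and 22517228 in WT replicates 1 to 3 and 23477911, 22533330 and 22375166 in lon1-2 replicates 1 to 3. The coefficient of biological variation was 11.1%. Within a genotype, counts of replicate pairs differed by 5.31 to 28.9 times the sampling variance, so no library was taken as a copy of another. In counts simulated for this comparison over 19922 genes, 66.3% of 98 genes changed 1.5-fold and 93.9% of 99 genes changed 2-fold were recovered, with 9 calls among unchanged genes. The simulation used the same dispersion for all genes and changed far fewer genes than were called in the real data.

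The comparison, the tests and the alternatives were fixed before the data were examined, as were 23 gene lists of 492 members: mitochondrial stress response, mitochondrial chaperones and proteases, mitochondrial translation and transcription, respiratory complexes, tricarboxylic acid cycle, protein import, cytosolic heat shock, endoplasmic reticulum unfolded protein response, photosynthesis, hypoxia, salicylic acid defence, jasmonate, iron, abscisic acid, auxin, anthocyanin, glucosinolate, starvation, antioxidants, and markers of dividing cells, seeds, roots and root hairs. In these lists 1 member was dropped because the annotation gives that locus as another gene, and 1 was not among the listed genes. HSP23.5, MGE2, TIM17-1, IRT1 and FRO2 are each in 2 lists. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 23 lists. Each camera call was lost when the correlation between genes was estimated from these 6 libraries. Fry, planned beside camera, asks whether a list's members changed and does not compare them with other genes. It gave adjusted p of 0.00153 to 0.00389 for the 6 mitochondrial lists, photosynthesis and anthocyanin. The hypoxia and iron lists, called by camera, did not pass fry (adjusted p = 0.101 and 0.0872). The abscisic acid and antioxidant lists, not called by camera, passed (adjusted p = 0.0331 and 0.0453).

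Genes were named by a rule fixed at the same time. It took LON1, and the 6 genes with the largest rise and the 6 with the largest fall among those with adjusted p under 0.05, a mean of at least 5 CPM in the higher genotype and no overlap between genotypes. It also took up to 3 members per list with the smallest p in the direction most called members took, and AOX1A, LON4, HSP23.5 and HSP60 always. Genes named for another reason are marked where they appear.

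Alternatives planned were other normalisations (DESeq2 size factors, upper quartile), other filters, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) or log2(FPKM + 0.1), the replicate number as a block, and leaving out each library. Total-count scaling and offsets for GC content and gene length were added after seeing the data.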

Results

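Messenger RNA was measured in whole 7-day-old seedlings of Arabidopsis thaliana, in the Columbia-0 wild type (WT) and in lon1-2, a T-DNA insertion mutant of LON1 in that background. LON1 encodes an ATP-dependent protease of the mitochondrial matrix. Each genotype was represented by 3 biological replicates grown under 16 h of light and 8 h of dark, giving 6 RNA-seq libraries. Total counts over the 27444 listed nuclear genes lay between 22517228 and 23226320 in WT and between 22375166 and 23477911 in lon1-2. Log expression correlated across genes with r of 0.981 to 0.993 within genotypes and 0.931 to 0.961 between them. The first principal component held 77.7% of the variance and separated the genotypes. The 43 genes of the nuclear photosynthesis list took 12.2% ± 0.365 of all counts in WT and 15.1% ± 0.294 in lon1-2 (SD, n = 3 each), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow.

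The targeted gene was examined first, since it checks the genotype labels. LON1 (AT5G26860) lies on chromosome 5 of TAIR10.1, from 9450952 to 9457000 on the plus strand, and its annotated exons form 19 blocks. Its counts were 608, 625 and 655 in the WT replicates and 65, 84 and 73 in the lon1-2 replicates. The normalised level was 26.0 ± 1.56 CPM in WT and 3.45 ± 0.469 CPM in lon1-2 (SD, n = 3 each), a log2 fold change of -2.91 with a standard error of 0.116 (adjusted p = 8.76e-06). The lon1-2 level was 13.3% of the WT level. Counts were summed over the gene, and the position of the insertion is not given in the sources used here, so the remaining reads could not be placed on either side of it.

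The main comparison asked which transcripts differed between seedlings with and without intact LON1. The largest rise among well-expressed genes was that of NDB4 (AT2G20800), an alternative NAD(P)H dehydrogenase of mitochondria, from 0.0835 ± 0.0848 to 14.8 ± 0.861 CPM (SD, n = 3 each; log2 fold change 7.39, standard error 0.315, adjusted p = 8.76e-06). It was followed by AT1G75945, an uncharacterised protein gene (log2 fold change 5.92), AT5G52940, a member of the DUF295 family (5.78), the NAC transcription factor gene NAC044 (4.24), ORA47, which encodes an AP2/ERF-type transcription factor (4.2), and AT5G24640 (4.1). The deepest falls were those of TPS12 (AT4G13280), a terpene synthase gene, from 14.1 ± 2.14 to 0.139 ± 0.0907 CPM (SD, n = 3 each; log2 fold change -6.60, standard error 0.289, adjusted p = 9.05e-06), and of AT4G04990 (log2 fold change -6.32). AT1G77520 and AT1G77530, both O-methyltransferase family genes, had log2 fold changes of -5.73 and -4.69. The metal reductase gene FRO5 fell from 21.8 ± 3.41 to 0.578 ± 0.276 CPM and the vegetative storage protein gene VSP1 from 15.9 ± 3.48 to 0.494 ± 0.131 CPM (SD, n = 3 each). Each of these 12 genes had adjusted p of 0.00067 or less, and its 3 values in the higher genotype lay above the 3 in the other. For the genes lowest in 1 genotype the size of the fold rested on few counts: without WT replicate 3 the log2 fold change of NDB4 was 8.34 and that of AT1G75945 was 6.57, and without lon1-2 replicate 1 that of AT4G04990 was -6.98.

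In total, 9195 of 19940 tested genes (46.1%) differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 4739 higher and 4456 lower in lon1-2. Of these, 2145 changed at least 2-fold, 729 higher and 1416 lower, and 524 at least 4-fold, 156 higher and 368 lower. The 3 libraries of each genotype did not overlap for 58.8% of tested genes, against 10% by chance. The split between directions depended on the scaling. Scaling by total counts alone shifted the median log2 fold change of all genes from -0.01 to -0.18 and gave 2941 higher and 7465 lower genes, a higher share of 28.3% against 51.5%. Tests on the deposited FPKM, which are scaled in the same way, gave higher shares of 27.7% to 28.7%. At 2-fold or more, total-count scaling gave 515 higher and 1880 lower genes, and log2(FPKM + 1) gave 225 higher and 823 lower.

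**Figure D1:**
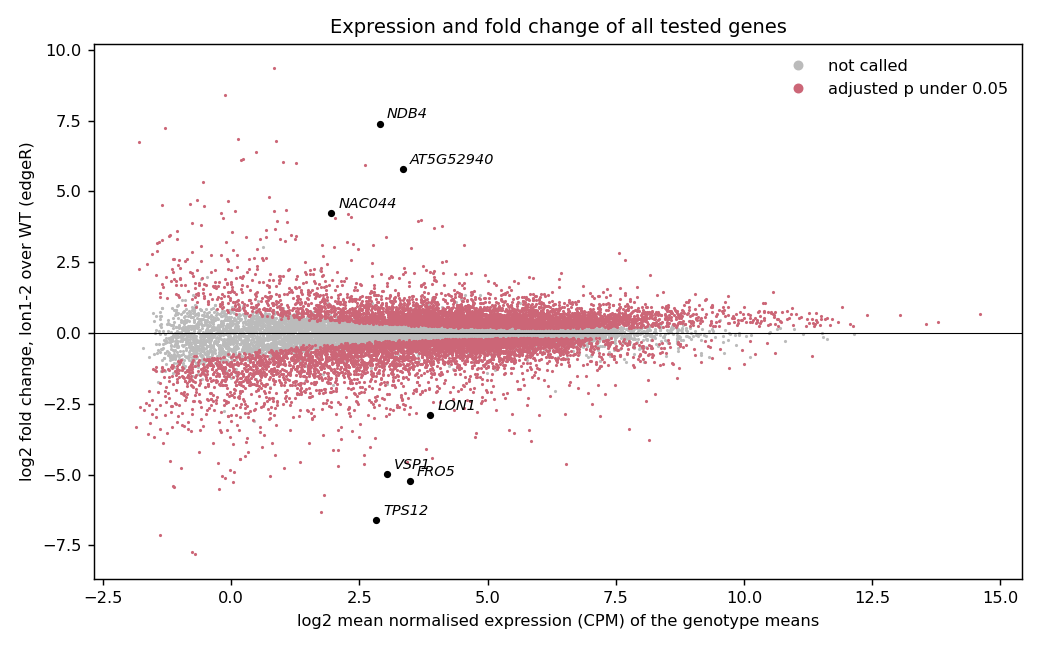
Each point is 1 of the 19940 tested genes, placed by the log2 of its mean CPM over both genotypes (horizontal axis) and its log2 fold change in lon1-2 over WT from edgeR (vertical axis), in red where the adjusted p is under 0.05. NDB4 at 7.39 and TPS12 at -6.60 are among the 7 labelled genes, and fitted values of genes with no counts in 1 genotype are not bounds on their fold.

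Genes of the mitochondrial stress response, which are induced through signals from impaired mitochondria, were mostly higher in lon1-2. Of 26 tested members of the list, 15 rose and 4 fell, and 16 and 4 did when adjusted over the list alone. AT12CYS-2, a small twin-cysteine protein gene, rose from 2.18 ± 0.686 to 28.8 ± 2.26 CPM, and NAC013, a transcription factor that activates this response, from 9.31 ± 0.64 to 25 ± 0.833 CPM (SD, n = 3 each). NDB4 is in this list too. AOX1A, the alternative oxidase gene in common use as a marker of the response, rose by a log2 fold change of 0.50 with a standard error of 0.116 (53.4 ± 6.25 to 75.6 ± 9.86 CPM, SD, n = 3 each; adjusted p = 0.0086). The 4 members that fell, named after their values were seen, were AOX1D, NDA2, GSTU24 and AT2G41380. The list's median log2 fold change was 0.67 and camera gave an adjusted p of 3.48e-11, or adjusted p = 0.327 with an estimated correlation. The AOX1A call was lost in log2(FPKM + 1) with every gene with an FPKM above 0 kept (log2 fold change 0.32, adjusted p = 0.0615).

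The list of mitochondrial chaperones and proteases held genes for protein folding and breakdown in the organelle. Of 31 tested members, 23 rose and 1 fell, with the same 23 and 1 counted when adjusted over the list alone. MTHSC70-1 and MTHSC70-2, the matrix HSP70 genes, rose from 82.5 ± 6.49 to 202 ± 13.3 CPM and from 31.0 ± 1.6 to 65.7 ± 4.88 CPM. HSP60 rose from 53.5 ± 6.96 to 115 ± 7.69 CPM, HSP60-2 from 32.8 ± 4.89 to 85.6 ± 4.74 CPM, and the small heat shock protein gene HSP23.5 from 2.05 ± 0.914 to 11.4 ± 1.92 CPM (SD, n = 3 each). LON4, a paralog of LON1, rose from 0.388 ± 0.183 to 3.75 ± 1.13 CPM (SD, n = 3 each), with a log2 fold change of 3.26 and a standard error of 0.368 (adjusted p = 0.00038). The member that fell, named after its value was seen, was CLPX1, a subunit gene of the Clp protease (log2 fold change -0.36). The median log2 fold change was 0.79 (camera adjusted p = 6.12e-12, or adjusted p = 0.327 with an estimated correlation), and under total-count scaling 19 members rose and 4 fell with a median of 0.62. For MTHSC70-2, 18.1% of exonic 50-mers occur elsewhere in the genome, and how its reads were assigned was not tested.

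**Figure D2:**
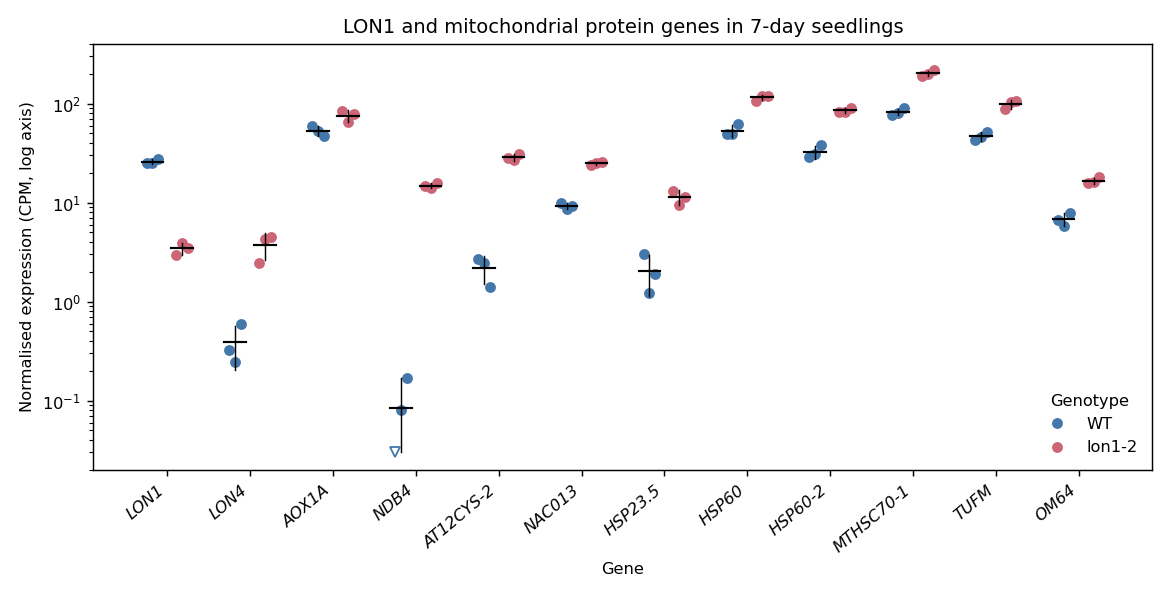
Normalised expression in CPM on a log axis for LON1 and 11 genes of mitochondrial proteins or their regulation, with 1 point per library, WT in blue and lon1-2 in red, horizontal bars for the mean of 3 and vertical bars for 1 SD; an open triangle at the foot marks a library with 0 counts. LON1 lies lower in all 3 lon1-2 libraries (mean 3.45 against 26.0 CPM) and the other 11 genes lie higher in all 3.

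Most members of the lists for making and importing mitochondrial proteins were called higher. In the list of mitochondrial ribosome, translation and transcription genes encoded in the nucleus, 14 of 18 tested members rose and 0 fell, and 15 rose when adjusted over the list alone. TUFM, the mitochondrial elongation factor Tu, rose from 46.8 ± 4.6 to 99.2 ± 10.2 CPM, RPOTMP, an organellar RNA polymerase, from 8.33 ± 0.284 to 16.0 ± 1.24 CPM, and HLL, a ribosomal protein gene, from 4.13 ± 0.583 to 11.4 ± 1.63 CPM (SD, n = 3 each). In the protein import list, 15 of 25 tested members rose and 0 fell, and 16 rose when adjusted over the list alone. OM64, an outer membrane receptor, rose by a log2 fold change of 1.3, and the intermembrane space chaperones TIM10 and TIM13 by 0.73 and 1.03. The medians were 0.60 and 0.48. Camera gave adjusted p of 6.05e-07 and 9.51e-05, or adjusted p = 0.331 and 0.327 with an estimated correlation. In log2(FPKM + 1), 10 import genes rose and 1 fell with a median of 0.17, and 14 translation and transcription genes rose and 1 fell with a median of 0.40. The genes encoded in the mitochondrial and plastid genomes were not analysed here.

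Most tested members of the respiratory lists were called higher under the main scaling. Of 73 tested nuclear genes of complexes I to V and cytochrome c, 49 rose and 0 fell, and 51 rose when adjusted over the list alone. Their median log2 fold change was 0.30 (camera adjusted p = 8.39e-07, or adjusted p = 0.327 with an estimated correlation). SDH4 of complex II rose from 47.6 ± 0.809 to 71.4 ± 2.1 CPM, GAMMA-CA2 of complex I from 69.4 ± 3.29 to 106 ± 5.22 CPM and ATP20B of the ATP synthase from 32.1 ± 0.851 to 49.6 ± 3.54 CPM (SD, n = 3 each). In the pyruvate dehydrogenase and tricarboxylic acid cycle list, 16 of 26 rose and 0 fell, and 17 rose when adjusted over the list alone. MTLPD1, lipoamide dehydrogenase, rose from 256 ± 7.08 to 466 ± 7.75 CPM, MMDH1, malate dehydrogenase, from 191 ± 22.8 to 363 ± 36.0 CPM and FUM1, fumarase, from 93.4 ± 0.419 to 132 ± 6.26 CPM (SD, n = 3 each). The median was 0.29 (camera adjusted p = 9.51e-05, or adjusted p = 0.327 with an estimated correlation). Both results depended on the scaling. With total counts alone, 22 respiratory genes rose and 5 fell with a median of 0.13, and 12 genes of the pyruvate dehydrogenase and cycle list rose and 0 fell with a median of 0.12; in log2(FPKM + 1) the counts were 24 and 4, and 11 and 0.

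Photosynthesis and flavonoid genes were mostly higher in lon1-2. In the photosynthesis list, 40 of 43 members rose and 0 fell, with 40 and 0 also when adjusted over the list alone. The light-harvesting genes LHCB3, LHCB2.3 and LHCB4.3 had log2 fold changes of 0.72, 1.17 and 1.03, and LHCB3 rose from 1871 ± 32.7 to 3075 ± 100.4 CPM (SD, n = 3 each). The median was 0.46 (camera adjusted p = 3.02e-11, or adjusted p = 0.327 with an estimated correlation). Under total-count scaling 26 members rose and 2 fell, and in log2(FPKM + 1) 25 rose and 1 fell. In the flavonoid and anthocyanin list, 11 of 12 members rose and 0 fell, with 11 also when adjusted over the list alone. DFR and LDOX, late enzymes of anthocyanin synthesis, rose from 10.5 ± 0.539 to 35.8 ± 5.88 CPM and from 6.76 ± 1.59 to 24.6 ± 0.398 CPM, and TT4, chalcone synthase, from 373 ± 16.9 to 746 ± 54.0 CPM (SD, n = 3 each). The median was 1.55 (camera adjusted p = 3.02e-11, or adjusted p = 0.327 with an estimated correlation).

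**Figure D3:**
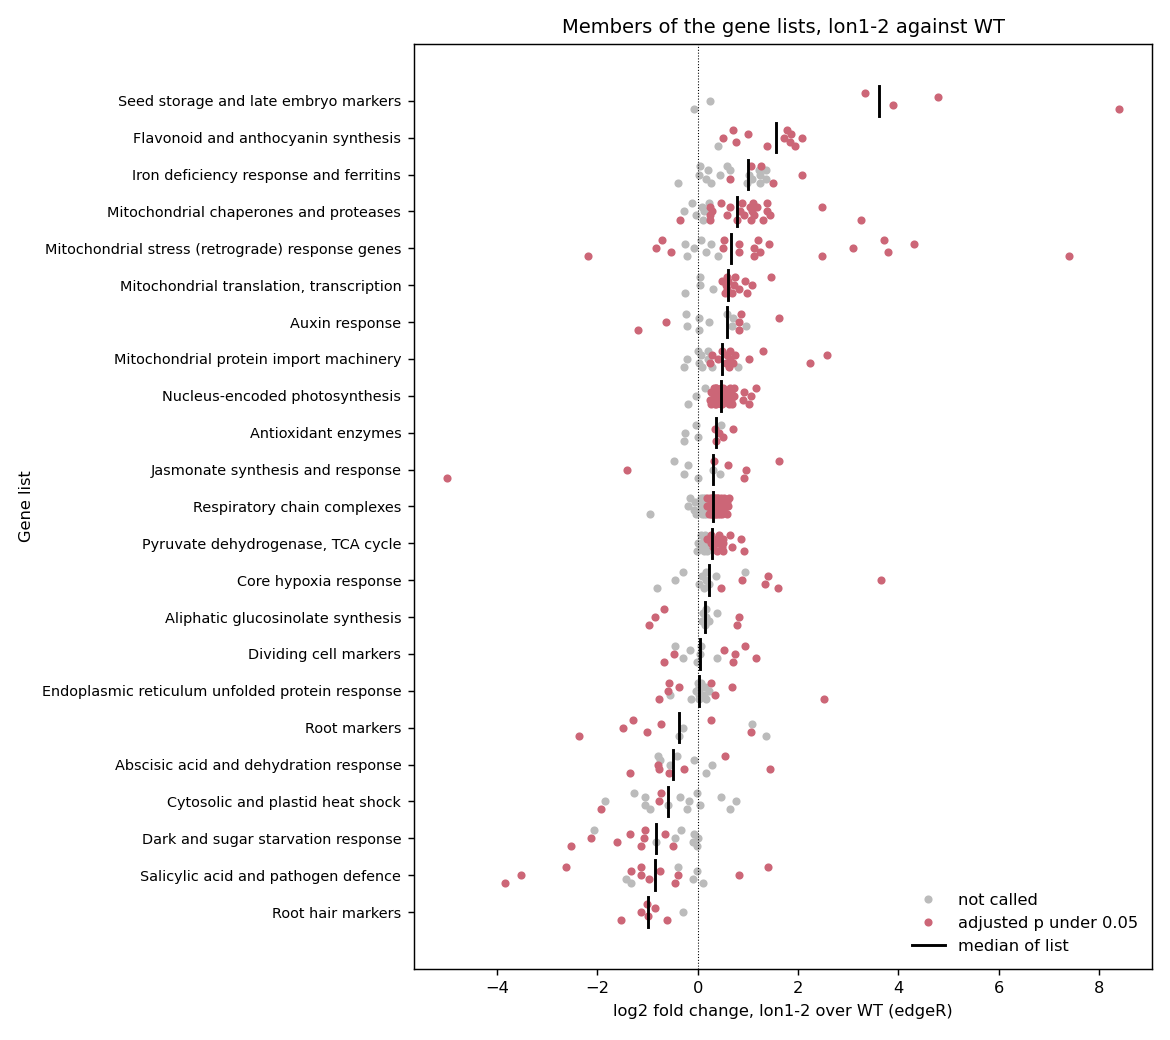
Log2 fold change in lon1-2 over WT (horizontal axis, edgeR) of each tested member of the 23 gene lists (vertical axis), with 1 point per gene, red where the adjusted p is under 0.05, and a black bar at each list's median. Medians run from 3.61 for the seed markers, where the SESA3 point is a fitted value against a genotype with no counts, to -0.99 for the root hair markers; the medians of the glucosinolate, dividing cell and endoplasmic reticulum lists turned below 0 under total-count scaling.

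More members were lower than higher in the defence and starvation lists. In the salicylic acid and pathogen defence list, 10 of 18 tested members fell and 2 rose, and 12 and 2 did when adjusted over the list alone. ALD1 and PBS3, enzymes of pipecolic acid and salicylic acid synthesis, had log2 fold changes of -3.84 and -2.62, and EDS5, a salicylic acid pathway transporter, had -0.96. The 2 that rose, named after their values were seen, were the WRKY transcription factor genes WRKY40 and WRKY53. The median was -0.85 (camera adjusted p = 0.00385, or adjusted p = 0.568 with an estimated correlation), and the camera call was lost in log2(FPKM + 1), with adjusted p = 0.0847. In the dark and sugar starvation list, 9 of 17 members fell and 0 rose, and 10 fell when adjusted over the list alone. IVD, an enzyme of leucine breakdown, fell from 78.3 ± 15.2 to 25.6 ± 6.20 CPM, ETFQO from 34.9 ± 1.71 to 24.8 ± 1.19 CPM and the glycosyl hydrolase gene DIN2 from 4.06 ± 1.55 to 1.6 ± 0.144 CPM (SD, n = 3 each). The median was -0.84 (camera adjusted p = 0.0021, or adjusted p = 0.568 with an estimated correlation). The number of members that fell was 4 without WT replicate 1, 4 without lon1-2 replicate 3, 5 with no expression filter and 14 in log2(FPKM + 1).

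In the iron deficiency and ferritin list, 5 of 22 members rose and 0 fell, with 5 also when adjusted over the list alone. The ferritin genes FER2, FER3 and FER4, which encode iron storage proteins, rose by log2 fold changes of 2.09, 1.07 and 0.64. The other members called, named after their values were seen, were NAS1 and NAS2, nicotianamine synthase genes. The median was 1.01 (camera adjusted p = 0.00869, or adjusted p = 0.568 with an estimated correlation), and without WT replicate 3 the number of members that rose was 9. In the core hypoxia list, 6 of 17 rose and 0 fell, with 6 also when adjusted over the list alone. HRE2, an ERF transcription factor gene, rose from 0.260 ± 0.0805 to 3.36 ± 0.383 CPM, HB1, a haemoglobin gene, from 17.7 ± 2.81 to 46.6 ± 7.75 CPM and PDC1, pyruvate decarboxylase, from 4.86 ± 0.420 to 12.4 ± 3.44 CPM (SD, n = 3 each). The median was 0.23 (camera adjusted p = 0.0161, or adjusted p = 0.676 with an estimated correlation). Under total-count scaling 6 hypoxia genes rose and 2 fell with a median of 0.06. The hypoxia call was lost without lon1-2 replicate 1 (adjusted p = 0.18) and in limma-voom (adjusted p = 0.0556).

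Markers of tissues and stages were examined because whole seedlings hold them in proportions that can differ. Of 7 root hair markers, 6 fell and 0 rose, also when adjusted over the list alone. RSL4, a regulator of root hair growth, fell from 4.26 ± 0.240 to 1.47 ± 0.0869 CPM, the expansin gene EXPA7 from 18.7 ± 2.11 to 10.4 ± 0.992 CPM and PRP3, a cell wall protein gene, from 111 ± 20.5 to 50.8 ± 6.90 CPM (SD, n = 3 each). The median was -0.99 (camera adjusted p = 0.000449, or adjusted p = 0.327 with an estimated correlation). Of 11 root markers, 5 fell and 2 rose, also when adjusted over the list alone, and camera gave an adjusted p of 0.305 with a median of -0.37. CASP1, CASP2 and ESB1, genes of the endodermal Casparian strip, fell, with log2 fold changes of -1.29, -1.50 and -1.01, while PYK10 and PBP1, named after their values were seen, rose by 0.27 and 1.07; under total-count scaling 1 root marker rose and 7 fell. PYK10 and PBP1 encode root proteins of the endoplasmic reticulum body system. The number of root markers called was 4 without WT replicate 2. Of 12 listed seed storage and late embryo markers, 6 were tested, of which 4 rose and 0 fell, also when adjusted over the list alone. SESA3, a seed albumin gene, had 0 counts in the 3 WT libraries and 24, 65 and 29 in lon1-2, at least 44.4-fold higher against a floor of 3 counts over the WT group. SESA3 thus passed the expression filter only through lon1-2. The number of seed markers tested, their median and the camera test therefore depend partly on the rise itself. CRA1, a cruciferin gene, rose from 0.344 ± 0.0629 to 3.5 ± 2.59 CPM (SD, n = 3 each), and its log2 fold change of 3.33 was 2.53 without lon1-2 replicate 2. The seed median was 3.61, also with SESA3 at its bound (camera adjusted p = 0.0121, or adjusted p = 0.432 with an estimated correlation), and the call was lost among genes with a mean CPM of 1 or more (adjusted p = 0.0808), while 7 seed genes rose with no expression filter. Of 14 dividing cell markers, 5 rose and 2 fell, also when adjusted over the list alone, with a camera adjusted p of 0.421. The replication genes PCNA1, PCNA2 and MCM2 rose by log2 fold changes of 0.95, 0.70 and 0.75, while CDKB2;2 and KN, which act in mitosis and cytokinesis and were named after their values were seen, fell, with -0.47 and -0.67. Under total-count scaling 4 of these markers rose and 4 fell, and the list's median turned from 0.06 to -0.11.

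The remaining lists did not pass the camera test, although single members changed. Of 17 cytosolic and plastid heat shock genes, 3 fell and 0 rose, also when adjusted over the list alone, with GOLS1 at a log2 fold change of -1.92 and HSFB1 at -0.73 (camera adjusted p = 0.15). Without lon1-2 replicate 1 this list passed, with adjusted p = 0.00956 and 6 members lower, but not with an estimated correlation (adjusted p = 0.634). Of 21 genes of the endoplasmic reticulum unfolded protein response, 4 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.741). NAC103, a transcription factor of that response, rose from 0.801 ± 0.355 to 4.61 ± 0.701 CPM (SD, n = 3 each), and DER2.1 and CRT3, genes of protein quality control, had log2 fold changes of -0.60 and -0.57. Without lon1-2 replicate 3, 5 members of this list were called, and its median of 0.02 was -0.15 under total-count scaling. Of 10 antioxidant enzyme genes, 5 rose and 0 fell (camera adjusted p = 0.142), and 5 and 1 did when adjusted over the list alone. The mitochondrial MSD1, PRXIIF and TRXO1 had log2 fold changes of 0.50, 0.37 and 0.43.

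Hormone and secondary metabolism lists went both ways. Of 13 jasmonate genes, 5 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.421). The synthesis genes LOX2, AOS and AOC2 rose by log2 fold changes of 1.62, 0.92 and 0.95, while VSP1 and VSP2, the latter named after its value was seen, fell, with -4.98 and -1.41, so that the list's median was 0.31 and its mean -0.16. Of 14 abscisic acid and dehydration genes, 5 fell and 2 rose, and 7 and 2 did when adjusted over the list alone, with KIN2, COR47 and RAB18 at -0.79, -0.77 and -1.35. Camera gave this list an adjusted p of 0.0985, which was 0.0103 without lon1-2 replicate 2 (adjusted p = 0.283 there with an estimated correlation), and the number of members called was 4 without WT replicate 2. Of 15 auxin response genes, 4 rose and 2 fell, and 3 and 2 did when adjusted over the list alone, with IAA1 at 0.82 and IAA29 at 1.61 (camera adjusted p = 0.278). The number of auxin genes called was 2 without WT replicate 2 and 3 without WT replicate 3 or lon1-2 replicate 2. Of 12 aliphatic glucosinolate genes, 2 rose and 3 fell, also when adjusted over the list alone. The 3 that fell were MAM1, CYP79F1 and CYP83A1, enzymes of the pathway, with log2 fold changes of -0.97, -0.85 and -0.67. This list's median of 0.15 and mean of 0.03 were above 0 while camera's direction was down (adjusted p = 0.914), and under total-count scaling the median was -0.02.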

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

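Total-count scaling, offsets for GC content and length, and the block with these offsets were chosen after seeing the data. The number of changed genes was within 1.5 times the reported one in every alternative, and no called gene was called in the opposite direction in any. Of the 9195 called genes, 6478 kept call and direction without lon1-2 replicate 3, 7397 under total-count scaling and 9130 with DESeq2 size factors. In log2(FPKM + 1), 6639 of the 8435 called genes tested there kept both. Leaving out 1 library gave 6588 (without lon1-2 replicate 3) to 10288 (without lon1-2 replicate 1) changed genes, 1905 to 2500 of at least 2-fold, and log2 fold changes of LON1 from -3.01 to -2.81. In log2(FPKM + 1) the log2 fold change of LON1 was -2.21, with either filter. The 2-fold count fell to 1048 in log2(FPKM + 1) and 1086 in log2(FPKM + 1) with any FPKM above 0 kept, and was 1647 in log2(FPKM + 0.1), so the pseudocount accounts for part of the fall; the cause of the rest was not tested. The replicate number was not taken to pair these samples, since the labels do not say so and 1 of 3 correlations was under 0.1. Deviations of same-numbered libraries correlated across genes at 0.314, 0.128 and 0.0917, and others at -0.304 to 0.208; WT replicate 3 correlated best with lon1-2 replicate 2 (0.208). With the number as a block, 9853 genes changed, 2186 of them at least 2-fold, LON1 had a log2 fold change of -2.91, and the cytosolic heat shock list passed with 10 members lower and 1 higher (adjusted p = 0.00184, or 0.416 with an estimated correlation; 0.00171, with 9 lower and 1 higher, with GC and length offsets too).

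For camera tests, adjusted p moved over the threshold for the seed markers (0.0808, mean CPM of 1 or more), hypoxia (0.0556, limma-voom) and salicylic acid lists (0.0847 and 0.0996, log2(FPKM + 1) and log2(FPKM + 0.1)); the cause was not tested. The direction turned, with no call either way, for the glucosinolate list in limma-voom (0.84), log2(FPKM + 1) (0.69), log2(FPKM + 0.1) (0.685), any FPKM above 0 (0.702), the replicate block (0.933), the block with offsets (0.993) and total-count scaling (0.995), and for the endoplasmic reticulum list in the 3 FPKM settings (0.778, 0.774 and 0.612); the cause was not tested. Leaving out 1 library gave ranges of 0.705 to 0.967 for glucosinolate, turned without WT replicate 1 (0.852) and lon1-2 replicate 1 (0.705), 0.541 to 0.877 for the endoplasmic reticulum list, turned without lon1-2 replicate 1, and 0.0694 to 0.877 for jasmonate, turned without WT replicate 3. Ranges were 1.71e-06 to 0.18 for hypoxia and 0.00956 to 0.417 for heat shock, both crossing without lon1-2 replicate 1, and 0.0103 to 0.163 for abscisic acid, crossing without lon1-2 replicate 2. Of 435 counts of called list members under alternatives, 31 moved by more than 1.5 times. Most named genes were picked for a small p or a large fold change in the main fit. Of 1586 values of named genes under alternatives, 1576 kept direction and call and 10 lost the call, all of AOX1A, SAUR21 or HSFA7A. HSFA7A lost it without any 1 of the WT replicates 1, 2 and 3 (0.0675, 0.0799, 0.0682) or lon1-2 replicate 3 (0.0742), and SAUR21 without WT replicates 2 or 3 (0.077, 0.0611), without lon1-2 replicates 2 or 3 (0.074, 0.0743) and under total-count scaling (0.0547). The alternative without organelle genes was not run, since no such genes were analysed. At this depth and with 3 libraries, simulated changes of 1.5-fold were recovered for 66.3% of genes, so smaller changes are detected less completely. The simulation changed far fewer genes than were called here, with the same dispersion for all, so this share need not hold for the real comparison.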

Other observations

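The tests of product families, the family weighing by shuffles, the scaling and dividing cell tests of the mitochondrial lists and both root marker tests were chosen after the results were seen, and the genes in the first 3 paragraphs were named after their values were seen. Genes were grouped by the product term of the annotation, which gave 190 families including 3 assembled by hand, and 27 had a camera adjusted p under 0.05, each of which lost that call with an estimated correlation (adjusted p = 0.718 or more). The DUF295 family, uncharacterised genes of which some encode organellar proteins, had 12 of 19 tested members higher and 3 lower, with a median log2 fold change of 2.01, also with members that had no WT counts at their bound (adjusted p = 2.18e-10, or adjusted p = 0.718 with an estimated correlation). Some of these passed the expression filter only through lon1-2, such as AT5G53240, with 0 CPM in WT and 0.822 ± 0.0435 CPM in lon1-2 (SD, n = 3 each). The count of tested members and their median thus depend partly on the rise itself. AT5G52930 rose from 0.0702 ± 0.0885 to 4.72 ± 0.539 CPM (SD, n = 3 each), and AT5G54560 had 0 counts in WT and 66, 84 and 79 in lon1-2, at least 86.1-fold higher against a floor of 3 counts over the WT group. Of 283 tested pentatricopeptide repeat genes, most of which act on organellar RNA, 97 rose and 9 fell (median 0.36, or 0.19 under total-count scaling, adjusted p = 0.000461, or adjusted p = 0.718 with an estimated correlation). Of 780 tested genes whose annotation places the product in mitochondria, 376 rose and 81 fell (median 0.26, or 0.09 under total-count scaling, adjusted p = 2.59e-07, or adjusted p = 0.718 with an estimated correlation).

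Families that fell included peroxidases (29 of 52 lower and 5 higher, median -0.65, adjusted p = 6.79e-07), disease resistance genes of the TIR-NBS-LRR class (31 of 56 lower and 0 higher, median -0.43, adjusted p = 0.00023) and proline-rich extensins (9 of 10 lower and 0 higher, median -0.80, adjusted p = 0.00226). Total-count scaling lowered the median of all genes and took these medians to -0.82, -0.60 and -0.96. It could not have turned their sign, so it does not test these falls. With an estimated correlation, the adjusted p of each of these 3 families was 0.718.

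Thalianol synthase and 3 genes near it were tested gene by gene and not as a set: THAS1 fell from 103 ± 15.6 to 9.57 ± 1.96 CPM, CYP708A2 from 78.5 ± 7.76 to 7.24 ± 1.34 CPM and CYP705A5 from 107 ± 19.1 to 7.55 ± 1.31 CPM (SD, n = 3 each), and AT5G47980 from 5.60 ± 1.02 to 1.42 ± 0.559 CPM (log2 fold change -1.97). ICL, isocitrate lyase of the glyoxylate cycle, rose from 1.55 ± 0.233 to 24.6 ± 9.06 CPM and MLS, malate synthase, from 2.46 ± 0.512 to 5.01 ± 1.1 CPM (SD, n = 3 each). Among 9 clock genes, CCA1 (log2 fold change -0.56, adjusted p = 0.00109) and TOC1 (-0.35, adjusted p = 0.00325) fell, and LHY was at -0.07 (adjusted p = 0.483).

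The first pattern weighed was the rise of the 6 mitochondrial lists, with 196 tested genes together. Total-count scaling, which moved the median of all genes most among the settings tried, does not account for it alone. Under that scaling the pooled median log2 fold change was 0.18 (bootstrap 95% interval 0.13 to 0.25), although its size depends on the scaling. With GC content and length trends removed the pooled median was 0.36 (0.32 to 0.44). Both intervals come from resampling genes as if independent and do not measure the spread between libraries. A larger share of dividing cells as the only cause would raise their markers alike only if each were expressed in dividing cells alone and evenly among them. The markers differed by more than their errors (Cochran's Q = 159.9 over 14 markers), and some fell. Cochran's Q rejects only equal changes, which markers of replication and of mitosis need not show, so it cannot decide on a larger share of dividing cells. The markers that fell would not do so through a larger share alone, but a part from it is not excluded. A response to the loss of LON1 stays open as a hypothesis, which a delay in growth or a different makeup of the seedlings could also give.

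The second pattern was the fall of root and root hair markers. A smaller share of root tissue as the only cause would lower these 18 genes alike only if each were expressed in root alone and evenly across it. Of them 11 fell and 2 rose, and they differed by more than their errors (Cochran's Q = 637.2). Since markers of different root cell types need not fall alike, this difference cannot decide on a smaller share. The 2 that rose under the main scaling would not do so through a smaller share alone. A smaller share together with changes in single genes could also give these values, so a part from it is not excluded. Cochran's Q cannot decide whether count scaling lowered these markers. A library factor moves every gene by the same amount, so the value is the same with or without it. The differences between these genes do not come from such a factor. Changes in certain root cell types, such as root hairs and endodermis, may underlie the fall and were not tested.

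The third pattern was the DUF295 family. Reads shared between near-identical copies are argued against, since the median share of exonic 50-mers found elsewhere in the genome was 0% over the 12 members that rose, and the highest 0.954%. When fold changes were shuffled among genes of like expression, 0% of 1000 shuffles gave any family a median as far from 0 (the farthest was 1.52). The shuffles took as given the members that passed the filter, some only through lon1-2. Shuffling also ignores correlation between genes, and with that estimated the adjusted p was 0.718. Chance co-variation of related genes therefore cannot be told apart from a family response.

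The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The split by genotype gave 9195 changed genes and 2145 of at least 2-fold, and 1 of the 10 splits, the real one, gave as many. The highest of the other splits gave 0 and 0 in edgeR, with 919 and 96 genes at an unadjusted p under 0.05. Each of these puts libraries of both genotypes in each group. A genotype difference therefore adds to their spread and lowers their counts, so they cannot show what chance alone would give.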
